A study of Bos taurus with 8 samples.

How the data were processed

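Gene expression was measured in polymorphonuclear leukocytes (PMNL, the neutrophil-rich fraction of blood) of 8 Holstein cows, 4 on each of the dry-period diets labelled M and S, at day -14 and day +7 around calving. Per the labels, 200 ng of total RNA per sample was labelled with Cy3 or Cy5 and hybridised to 2-colour Agilent bovine arrays. The average RNA integrity number was 7.7 ± 0.2 over all samples. The scanner, the image software, the background method, the spot filter and the slide on which each array lay are not given in the sources used here.

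The deposited values are log2 ratios of the 2 channels of each array, with 43803 features on each of 8 arrays. They were not normalised. For 97.8 to 98.5% of the values, 2 to the power of the value was the ratio of 2 whole numbers of at most 10000 (tolerance 1e-09 on the log2 scale). After the values of an array had been shifted, only 0.8 to 1.2% were. The largest recovered intensities, 65465 to 65487, lay just under the 16-bit limit of 65535. Column medians ran from -0.37 to 0.40, and the ratios followed spot brightness, as the plot of log ratio against brightness shows. Blank values made up 25.6 to 36.8% of an array's features. The recovered whole numbers gave a brightness for each spot, a lower bound because ratios were reduced to lowest terms (in simulated spots the shortfall had a median of 0 and a 90th percentile of 2.32 on the log2 scale).

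Neither the labels nor the files state whether the ratios are Cy5 over Cy3 or Cy3 over Cy5. All signs are given with the ratio read as Cy5 over Cy3. If it is Cy3 over Cy5 in all 8 columns, every sign turns over, while sizes, errors, counts past a threshold and p-values stay. That all 8 columns have the same dye on top is an assumption. If the columns were mixed, sizes, errors, counts and p-values would change too. Among the 128 sign patterns of the 8 columns, this one ranked 17 by residual sum of squares with a dye term and 12 without it, over 9055 bright rows. Some mixed patterns thus left a smaller residual sum, and the ranks do not settle the question.

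The design fixed before the data were examined took the ratios as normalised. Because they were not, and before any model was fitted, each array was corrected by loess of the log ratio on the feature's median brightness (span 0.4, degree 1, 4 iterations); the values as deposited were kept as an alternative. Features with a value on all 8 arrays were used (19981 of 43803). Symbols came from the platform's annotation, updated through the RefSeq gene table of assembly ARS-UCD2.0, which was used for names only: 30788 features received 1 symbol and 13015 received none. Features of 1 symbol were averaged, which left 13080 rows, 8503 of them with a symbol. Among 4213 genes with several features, between 24.0 and 46.8% had features that differed in sign, depending on the comparison.

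A loop model was fitted with limma 3.58.1 in R 4.3.3. It had a term for each of the 4 groups of diet and day relative to a reference group, and a dye term, which left 4 residual degrees of freedom (prior degrees of freedom 3.63). 7 comparisons were tested: the diets at each day, the days in each diet, the interaction, and the averages of both. The threshold was an adjusted p of 0.05 (Benjamini-Hochberg over all rows), two-sided. Values are log2 changes ± the moderated standard error (SE) of the fit over 8 arrays. The p-values measure the spread between these arrays only. All arrays had equal weight, although their SD after loess ran from 0.58 to 1.49. The median SE was therefore 0.3415 for each comparison of 2 groups, whatever the spread of its own arrays. The 654 rows set beside each count at an unadjusted p under 0.05 are 5% of the rows tested. That is what chance gives only for independent rows, and other splits of the cows gave 81 to 5289 for diet at day +7. A fit with the cow as replicate block, by generalised least squares (correlation of 2 samples of a cow 0.22), stands beside the averages.

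27 gene lists were fixed before the data were examined and tested with limma's camera (preset correlation 0.01), adjusted over the lists of a comparison; camera with an estimated correlation and fry were run beside it. Fry tests whether the members of a list move, on balance, in 1 direction, without reference to other genes. The lists on Toll-like receptor (TLR) signalling, oxidative phosphorylation, fatty acid synthesis, proteasome and RNA polymerase were chosen knowing that the study looked at such pathways in these samples, so their results are not independent evidence. Named genes were fixed by rule: rows with a symbol past the threshold with the same sign on both direct arrays, or, where fewer than 10 passed, the 10 with the smallest p; within each list the 4 members with the smallest p; and a fixed panel of neutrophil genes. Panel genes with no row with values on all 8 arrays are not reported.

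The fit was tested on simulated data with 200 changed rows of 13080, in 10 runs. The noise was drawn independently for each row and array, with no correlation of genes or cows and equal spread on all arrays. Recovery and false calls in the real data can therefore differ. For diet at day +7 it recovered 3.18% of changes of log2 1, 50.1% of log2 2 and 87.6% of log2 4, with 5.3 false calls among 99.7. For day in diet M it recovered 3.03%, 50.6% and 86.9% of the same sizes, with 4.6 false calls among 98.7. Alternatives covered normalisation, scaling, the dye term, the cow block, the row definition, the blank filter, the threshold, direct arrays only and each array left out in turn. Loess on each array's own brightness, brightness minimums, a brightness trend in the variance, fry under other settings, and a run without both arrays of cow 8041 were added after the data had been seen. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.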

Results

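PMNL were taken from 8 cows, 4 on diet M and 4 on diet S, at day -14 and day +7, which gave 16 RNA samples from 4 cows in each of 4 groups. The labels describe a diet rich in wheat straw (1.34 Mcal/kg, at least 100% of the calculated energy need) and a corn silage diet (1.62 Mcal/kg, over 140%), fed during a dry period of 45 days. They do not say which of these is M and which is S. Each RNA sample was hybridised once. Of the 8 arrays, 2 paired the diets at day -14, 2 paired them at day +7, 2 paired the days in diet M and 2 paired the days in diet S, with the dyes exchanged inside each pair of arrays. In diet M each array held both days of 1 cow, whereas in diet S its 2 days came from different cows. The arrays gave a value for 27679 to 32580 features, and the median brightness ran from 27.9 to 74.5 per array. The number of arrays limits the precision.

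Signs below are diet M minus diet S, or day +7 minus day -14, with the ratios read as Cy5 over Cy3. On that reading a positive value is higher in diet M or at day +7; on the other reading it is higher in diet S or at day -14.

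**Figure D1:**
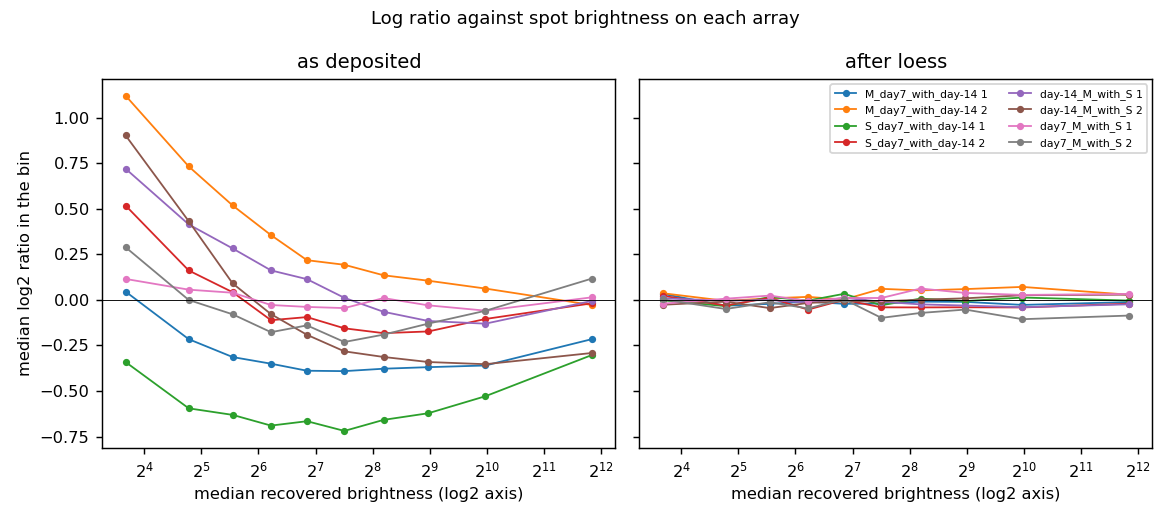
Median log2 ratio (vertical axis) of features in 10 bins of median recovered brightness (horizontal log2 axis), 1 line per array, as deposited on the left and after loess correction on the right. As deposited, the lines bend with brightness; after the correction they lie near 0.

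At day +7, the question was whether the diet before calving went with another leukocyte transcriptome after it. Ribosomal protein genes formed the most uniform difference: all 61 measured members were negative, with a median log2 of -0.85 (SD over members 0.25). Genes of oxidative phosphorylation, the mitochondrial machinery of ATP production, were mostly negative too, 66 of 74, with a median of -0.60 (SD 0.40). Interferon-stimulated genes, the antiviral programme, lay on the opposite side, positive in 22 of 23 with a median of 1.33 (SD 0.78). These lists had the same sign on both arrays that set the diets side by side at day +7: -0.41 and -1.10 for ribosomal proteins, -0.46 and -0.60 for oxidative phosphorylation, and 1.54 and 0.88 for interferon-stimulated genes. The second array of each pair carried RNA of cow 8041.

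Among ribosomal proteins, RPS6 was at -1.42 ± 0.35, RPL3 at -1.30 ± 0.34 and RPL24 at -1.26 ± 0.29. In oxidative phosphorylation, UQCRH of complex III was at -1.10 ± 0.26 and the ATP synthase subunit ATP5PO at -1.06 ± 0.26. The TCA cycle list was negative in 19 of 21 (median -0.52, SD 0.48), with DLD at -1.49 ± 0.37 and fumarate hydratase, FH, at -1.10 ± 0.28. The proteasome list was negative in 34 of 39 (median -0.44, SD 0.43), with PSMD1 at -1.07 ± 0.31, while its inhibitor subunit PSMF1 was at 1.25 ± 0.48. RNA polymerase subunits were negative in 20 of 24 (median -0.62, SD 0.53), among them POLR3G at -1.70 ± 0.45. Fatty acid and cholesterol synthesis was negative in 17 of 22 (median -0.63, SD 0.63), with the desaturase SCD at -1.31 ± 0.43 and SQLE at -1.20 ± 0.31. Cell cycle genes were negative in 18 of 24 (median -0.88, SD 0.78), with TPX2 at -1.63 ± 0.43 and CCNB2 at -1.44 ± 0.36. The cell cycle medians on the direct arrays were -0.06 and, with cow 8041, -1.32.

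On the positive side, interferon-stimulated genes included ISG20 at 2.32 ± 0.34, HERC6 at 2.22 ± 0.26, IFIT5 at 2.00 ± 0.33 and IRF9 at 1.76 ± 0.29. TLR and NF-kB signalling was positive in 26 of 32 (median 0.66, SD 0.79), with TLR8 at 2.29 ± 0.43 and the adaptor MYD88 at 2.33 ± 0.29. Adhesion and chemotaxis was positive in 18 of 20 (median 0.85, SD 0.98), with the selectin ligand SELPLG at 2.35 ± 0.37 and the complement receptor C5AR1 at 2.70 ± 0.53. Inflammatory cytokines and chemokines were positive in 13 of 17 (median 1.38, SD 1.17), with IL1B at 2.90 ± 0.48 and its antagonist IL1RN at 2.27 ± 0.44. Mature neutrophil markers were positive in all 12 (median 1.21, SD 0.99), with MXD1 at 2.70 ± 0.39 and VNN2 at 2.11 ± 0.52. Glucocorticoid-responsive genes were positive in 15 of 19 (median 0.72, SD 1.14), with SGK1 at 2.84 ± 0.51 and TSC22D3 at 2.15 ± 0.38. Of the lists for other cell types, 3 passed on the positive side, with monocyte markers positive in all 12 (median 0.77, SD 0.80; CD68 at 2.55 ± 0.45), eosinophil and basophil markers in all 6 (median 2.14, SD 1.25; GATA2 at 3.64 ± 0.77) and T cell and NK markers in 19 of 21 (median 0.48, SD 0.58; GZMB at 2.20 ± 0.57). On the direct arrays, the second with cow 8041, the medians were -0.52 and 2.71 for monocyte markers, -0.46 and 5.36 for eosinophil and basophil markers and 0.21 and 1.03 for T cell and NK markers. They were 0.15 and 2.19 for adhesion, 0.28 and 2.20 for glucocorticoid-responsive genes and 0.52 and 2.41 for cytokines. Mature neutrophil markers had 0.59 and 2.15, and TLR signalling 0.28 and 1.01. B cell markers were negative in 11 of 14.

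These 16 lists passed camera with the preset correlation. The adjusted p was 5.83e-15 for ribosomal proteins, 8.07e-10 for oxidative phosphorylation and 6.4e-08 for interferon-stimulated genes. It was 0.00011 for adhesion, 0.000138 for TLR signalling, 0.000182 for mature neutrophil markers, 0.000697 for both the TCA cycle and cytokines, 0.00196 for both RNA polymerase and proteasome, and 0.00261 for glucocorticoid-responsive genes. It was 0.00414 for fatty acid and cholesterol synthesis, cell cycle and monocyte markers, 0.0176 for eosinophil and basophil markers and 0.0234 for T cell and NK markers. None of the 16 passed with a correlation estimated from the data: adjusted p = 0.44 with an estimated correlation for most, 0.459 for adhesion and for cell cycle, 0.544 for monocyte and 0.658 for T cell and NK markers. Fry passed for 6 lists: oxidative phosphorylation (adjusted p = 0.0211), TCA cycle and proteasome (0.029 each), and TLR signalling, interferon-stimulated genes and ribosomal proteins (0.0416 each). Without both arrays of cow 8041 fry passed for 0 of 27 lists. That loss was not particular to this cow. Fry also passed for 0 lists without any single array lacking that cow, except 3 without the second day -14 diet array. It passed for 1 list without the cow's day +7 array. Leaving arrays out also lowers the residual degrees of freedom. Camera, without both arrays of cow 8041, was lost for monocyte (median 0.11, adjusted p = 0.149), eosinophil and basophil (0.34, adjusted p = 0.249) and T cell and NK markers (0.25, adjusted p = 0.149).

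The other 11 lists did not pass camera at day +7. B cell markers had a median of -1.17 (adjusted p = 0.106), platelet markers 1.10 (0.111), apoptosis and survival 0.33 (0.154), eicosanoid synthesis 1.10 (0.17) and neutrophil granule and antimicrobial proteins 0.51 (0.281). Glycolysis had a median of 0.46 (0.398), unfolded protein response and heat shock 0.17 (0.441) and NADPH oxidase and antioxidants -0.01 (0.692). Fatty acid oxidation and PPAR targets (-0.09), MHC class II presentation (-0.18) and red blood cell markers (0.06) each had an adjusted p of 0.979. For NADPH oxidase, fatty acid oxidation and MHC class II the median and the mean differed in sign, and for NADPH oxidase, MHC class II and red blood cell markers the median and camera did. On the array with cow 8041 the granule list had a median of 2.36 and on the other array -1.40; platelet markers had 2.92 and -0.50, eicosanoid synthesis 2.08 and -0.31, glycolysis 1.42 and -0.43 and B cell markers -2.62 and 0.63. Without both of that cow's arrays the medians were 0.07 for eicosanoid synthesis, 0.02 for apoptosis, 0.15 for glycolysis, 0.29 for granule proteins and -0.58 for B cell markers.

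Gene by gene, limma called 1 of 13080 rows at day +7, a feature with no symbol (ID 24090) at 3.84 ± 0.31 (adjusted p = 0.0329), with 3.44 and 4.29 on its direct arrays; the rule for names did not cover it and it was singled out after its value was seen. At an unadjusted p under 0.05 there were 3760 rows, 1911 positive and 1849 negative, where 5% of the rows is 654. No gene with a symbol passed over all rows. Those with the smallest p, each at an adjusted p of 0.056, were the ADP receptor P2RY12 (3.80 ± 0.43), the inflammasome sensor NLRP3 (3.41 ± 0.36), RUFY4, the death receptor FAS (2.95 ± 0.37), OLIG1, SLC45A4, the triglyceride enzyme DGAT2 (2.52 ± 0.31), MYD88, PBX4 and HERC6, all positive. Adjusted over the list alone, 41 ribosomal protein genes and 17 oxidative phosphorylation genes passed, all negative, and so did 13 interferon-stimulated, 8 TLR, 7 adhesion, 7 cytokine, 7 glucocorticoid-responsive and 6 mature neutrophil genes, all positive. Cell cycle had 8 negative and 1 positive gene past it, unfolded protein response and heat shock 5 positive and 3 negative, B cell markers 1 of each sign, the TCA cycle 2 negative and granule proteins 1 negative. Apoptosis had 4, monocyte markers, NADPH oxidase and eicosanoid synthesis 3 each, glycolysis and eosinophil and basophil markers 2 each and fatty acid oxidation 1, all positive. The counts for oxidative phosphorylation and TLR are not independent evidence. In the neutrophil panel, TLR4 was at 2.14 ± 0.52, TLR2 at 0.88 ± 0.31, CXCL8 at 1.43 ± 0.85, NFKB1 at 0.61 ± 0.27, LTF at -0.86 ± 0.61, IL1R2 at -0.61 ± 1.07, S100A8 at 0.24 ± 0.77 and S100A9 at 0.48 ± 0.84; none passed. The count of 1 was 0 to 64 as each array was left out, 0 without both arrays of cow 8041 (1348 rows at the unadjusted threshold), 43 with the values as deposited and 361 among features with a median brightness of at least 64. At that minimum 320 of the calls were positive and 41 negative.

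**Figure D2:**
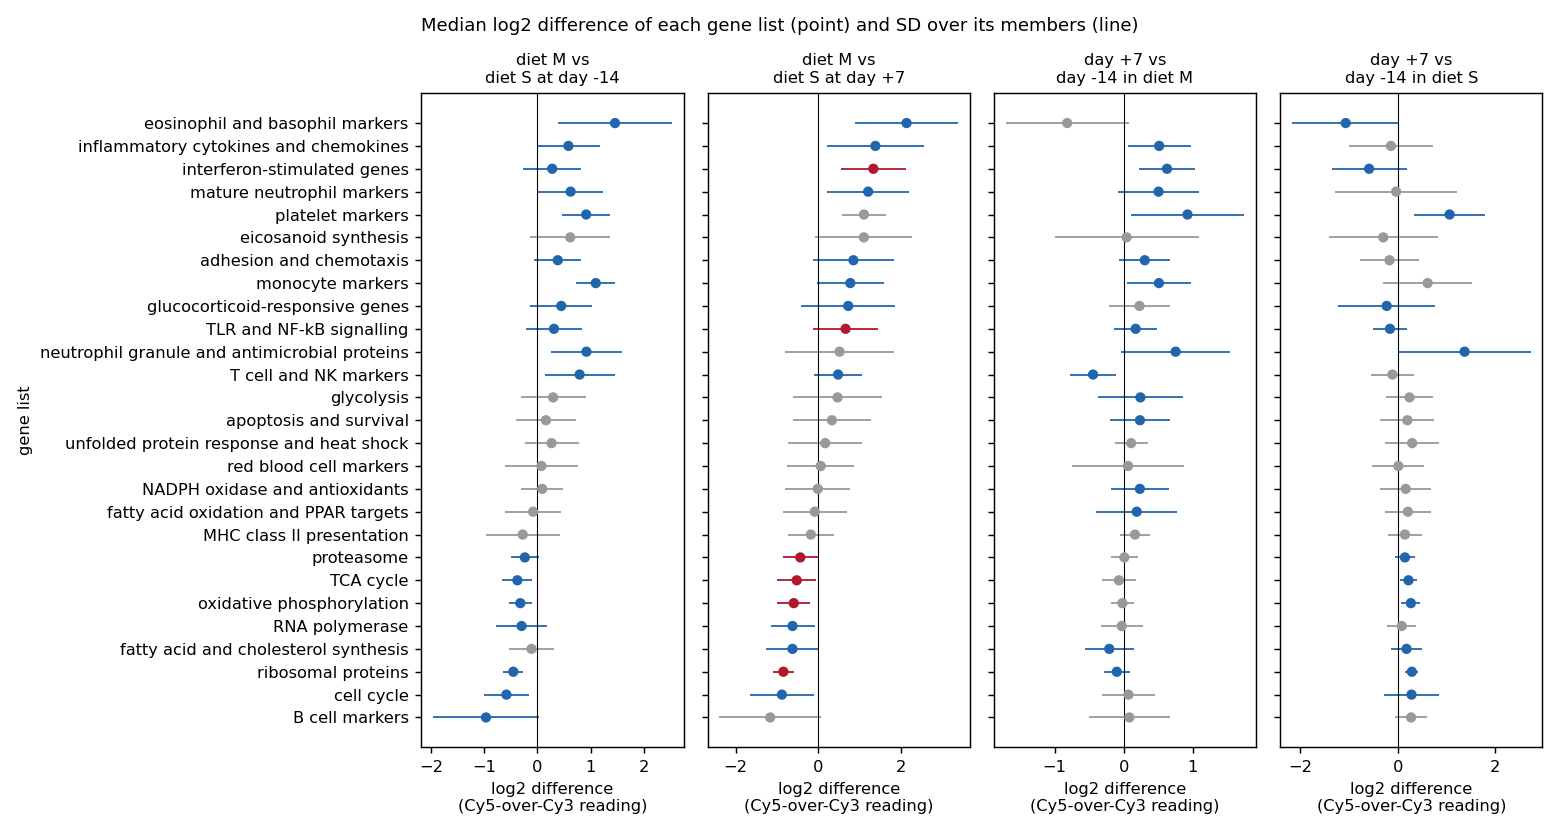
Median log2 difference of the members of each of 27 gene lists (points, horizontal axis) with the SD over members (lines), for 4 comparisons read as Cy5 over Cy3. Red marks lists that passed fry and camera, blue those that passed camera with the preset correlation alone, grey those that passed neither; red appears for 6 lists in diet M versus diet S at day +7.

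At day -14, while the diets were being fed, the same comparison asked whether the leukocytes already differed before calving. Ribosomal protein genes were negative in 60 of 61 (median -0.45, SD 0.19) and oxidative phosphorylation genes in 66 of 74 (median -0.32, SD 0.22). T cell and NK markers were positive in 19 of 21 (median 0.79, SD 0.66) and monocyte markers in all 12 (median 1.10, SD 0.37). Both direct arrays had these signs: -0.45 and -0.59 for ribosomal proteins, -0.32 and -0.43 for oxidative phosphorylation, 0.21 and 1.15 for T cell and NK markers, and 0.67 and 1.05 for monocyte markers.

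RPL3 was at -0.93 ± 0.34 and RPL4 at -0.78 ± 0.34, NDUFV1 of complex I at -0.77 ± 0.31 and UQCRH at -0.62 ± 0.26. Cell cycle genes were negative in 20 of 24 (median -0.58, SD 0.43; BUB1 at -1.09 ± 0.34), RNA polymerase subunits in 19 of 24 (median -0.29, SD 0.48; POLR3G at -1.80 ± 0.45), TCA cycle genes in 17 of 21 (median -0.37, SD 0.28) and proteasome genes in 33 of 39 (median -0.24, SD 0.26). The cytotoxic enzyme GZMB was at 1.98 ± 0.57, the T cell kinase ZAP70 at 1.73 ± 0.36 and MS4A7 of the monocyte list at 1.24 ± 0.47. TLR signalling was positive in 25 of 32 (median 0.31, SD 0.53; TLR8 at 1.25 ± 0.43), cytokines in 15 of 17 (median 0.58, SD 0.60; IL1B at 1.25 ± 0.48), adhesion in 18 of 20 (median 0.38, SD 0.44) and mature neutrophil markers in 9 of 12 (median 0.62, SD 0.61). Granule and antimicrobial proteins were positive in 19 of 20 (median 0.92, SD 0.67), glucocorticoid-responsive genes in 15 of 19 (median 0.45, SD 0.58), eosinophil and basophil markers in all 6 (median 1.46, SD 1.07; 2.80 and -0.27 on the direct arrays) and platelet markers in all 7 (median 0.92, SD 0.45). Interferon-stimulated genes were positive in 14 of 23 (median 0.28, SD 0.55; IFI44 at 1.47 ± 0.32), and B cell markers were negative in 11 of 14 (median -0.96, SD 0.99).

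Camera passed for these 18 lists, with an adjusted p of 9.46e-12 for ribosomal proteins, 9.57e-08 for oxidative phosphorylation, 5.31e-06 for T cell and NK markers, 6.94e-05 for monocyte markers, 0.00034 for cell cycle and 0.000558 for RNA polymerase, up to 0.0476 for interferon-stimulated genes. None passed with a correlation estimated from the data: adjusted p = 0.489 with an estimated correlation for most, and 0.512 for adhesion, granule proteins, B cell, platelet and interferon-stimulated genes. Fry passed for 0 of 27. Limma called 0 of 13080 rows, and 0 in each alternative. At an unadjusted p under 0.05 there were 804 (397 positive, 407 negative), where 5% of the rows is 654. The unadjusted count was 719 as deposited and 368 without both arrays of cow 8041. Adjusted over the list alone, 1 gene passed in each of 3 lists: ZAP70, GATA2 (3.46 ± 0.77) and IFI44. Those with the smallest p, each at an adjusted p of 0.703, also included the DNA polymerase subunit POLE2 (-2.27 ± 0.40), SLC20A2 (2.12 ± 0.33), EMP2 (-1.87 ± 0.39) and NLRP3 (1.66 ± 0.36). In the panel TLR4 was at 1.18 ± 0.52, TLR2 at 0.89 ± 0.31 and LTF at 1.12 ± 0.61. When the arrays of cow 8041 were left out, camera passed for 12 of the 18 lists; granule proteins (median 0.42, adjusted p = 0.294), B cell markers (-0.55, adjusted p = 0.165), platelet markers (0.30, adjusted p = 0.244), cytokines (0.35, adjusted p = 0.0771), adhesion (0.22, adjusted p = 0.0519) and glucocorticoid-responsive genes (0.34, adjusted p = 0.0747) were lost, while the medians of monocyte markers and of eosinophil and basophil markers were 0.54 and 0.89. 10 lists passed without the second array of the diets at day -14. With the cow as block, interferon-stimulated genes were lost (adjusted p = 0.0502).

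In diet M, the day comparison asked how PMNL differed after calving from before it, within 1 diet. Interferon-stimulated genes were positive in all 23 (median log2 0.62, SD 0.40), with 1.16 and 0.44 on the direct arrays. Mature neutrophil markers were positive in all 12 (median 0.50, SD 0.58), with 0.83 and 0.71. T cell and NK markers were negative in 18 of 21 (median -0.44, SD 0.33), with -1.03 and -0.13. OAS1Y, an antiviral sensor gene, was at 1.58 ± 0.40, HERC6 at 1.10 ± 0.26 and IFI44 at 0.85 ± 0.32. The neutrophil genes PROK2 and ALPL were at 1.81 ± 0.58 and 1.89 ± 0.71, and ZAP70 and CD7 at -0.91 ± 0.36 and -0.82 ± 0.34.

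Granule and antimicrobial proteins were positive in 19 of 20 (median 0.75, SD 0.79), with the cathelicidin CATHL2 at 2.53 ± 1.60 and haptoglobin, HP, at 2.35 ± 1.49. On the direct arrays CATHL2 was at 2.42 and 0.46, both below its estimate, and HP at 0.59 and 2.56. Without both arrays of cow 8041, CATHL2 was at 0.90 and HP at 0.88, so these sizes rest largely on that cow's arrays. Fatty acid oxidation and PPAR targets were positive in 19 of 24 (median 0.19, SD 0.58), with PDK4, the brake on pyruvate oxidation, at 2.34 ± 0.84 and CPT1A at 1.49 ± 0.59. Adhesion was positive in 18 of 20 (median 0.30), platelet markers in all 7 (0.92), NADPH oxidase in 16 of 22 (0.23), cytokines in 13 of 17 (0.51), monocyte markers in 11 of 12 (0.51), glycolysis in 19 of 22 (0.24), apoptosis in 17 of 23 (0.23) and TLR signalling in 21 of 32 (0.17). Ribosomal proteins were negative in 45 of 61 (-0.10) and fatty acid and cholesterol synthesis in 16 of 22 (-0.21). The direct arrays had opposite signs for NADPH oxidase (-0.04 and 0.47), glycolysis (-0.19 and 0.50) and fatty acid oxidation (-0.05 and 0.34).

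Camera passed for these 15 lists, with an adjusted p of 2.06e-09 for interferon-stimulated genes, 8.15e-05 for mature neutrophil markers, 0.0001 for T cell and NK markers, 0.000348 for granule proteins, and between 0.00412 (adhesion) and 0.0499 (TLR signalling) for the rest. None passed with a correlation estimated from the data: adjusted p = 0.692 with an estimated correlation, and 0.722 for ribosomal proteins. Fry passed for 0 of 27. Limma called 0 of 13080 rows, and 0 in each alternative. At an unadjusted p under 0.05 there were 272 (162 positive, 110 negative), fewer than the 654 that are 5% of the rows. The unadjusted count was 663 as deposited and 253 without both arrays of cow 8041. The smallest p, each at an adjusted p of 0.999, belonged among others to LOC618087 (3.14 ± 0.63), DLGAP3 (2.49 ± 0.35), OLIG1 (1.75 ± 0.29) and ASMT (-1.39 ± 0.32). LTF was at 1.16 ± 0.61 and S100A9 at 1.18 ± 0.84. Of the 15 lists, the interferon-stimulated, mature neutrophil and T cell and NK lists (the last with a median of -0.88) passed without both arrays of cow 8041, as did eosinophil and basophil markers (-0.82 and adjusted p = 0.0992 with them, -1.42 and adjusted p = 0.000139 without), and the other 12 of the 15 did not, among them granule proteins (median 0.38, adjusted p = 0.2), platelet markers (0.38, adjusted p = 0.291) and monocyte markers (-0.02, adjusted p = 0.983); no array of this diet's day pair carried that cow. With the cow as block 12 of the 15 passed, and TLR signalling (adjusted p = 0.0521), fatty acid oxidation (0.0545) and apoptosis (0.0639) were lost. With single arrays left out, 8, 7, 5 and 6 lists passed without the first day -14 diet array, the first diet S day array, the second diet M day array and the second day +7 diet array.

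In diet S, the same question was asked of the days. Ribosomal proteins were positive in 59 of 61 (median log2 0.29, SD 0.13) and oxidative phosphorylation genes in 68 of 74 (median 0.27, SD 0.19). Granule and antimicrobial proteins were positive in 16 of 20 (median 1.38, SD 1.36). Interferon-stimulated genes were negative in 17 of 23 (median -0.59, SD 0.77). On the direct arrays, the first of which carried cow 8041, the medians were 0.04 and 0.66 for ribosomal proteins, 0.27 and 0.37 for oxidative phosphorylation, 3.88 and -1.06 for granule proteins, and -0.44 and -1.08 for interferon-stimulated genes.

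RPL24 was at 0.59 ± 0.29 and the complex IV subunit COX6C at 0.52 ± 0.26. The iron-binding granule protein lactoferrin, LTF, was at 3.14 ± 0.61, the cathelicidin CATHL6 at 3.40 ± 1.15, MMP9 at 2.58 ± 1.07 and LCN2 at 1.89 ± 0.47. These sizes rest largely on the array with cow 8041. There, and then on the other direct array, LTF was at 5.61 and 0.64 and LCN2 at 3.47 and 1.14. CATHL6, at 8.23 and -0.74, and MMP9, at 4.72 and -0.27, had opposite signs. IFIT2 was at -1.90 ± 0.61, ISG20 at -1.25 ± 0.34 and STAT2 at -1.04 ± 0.34, whereas IFI44 was at 1.11 ± 0.32. TLR signalling was negative in 24 of 32 (median -0.16; MYD88 at -0.93 ± 0.29) and glucocorticoid-responsive genes in 13 of 19 (-0.22; SGK1 at -1.86 ± 0.51). Eosinophil and basophil markers were negative in 5 of 6 (-1.07). TCA cycle genes were positive in 19 of 21 (0.22), proteasome genes in 31 of 39 (0.15), cell cycle genes in 16 of 24 (0.29; CDC20 at 1.04 ± 0.39), platelet markers in 6 of 7 (1.07) and fatty acid and cholesterol synthesis in 17 of 22 (0.18). The direct arrays had opposite signs for platelet markers (3.73 with cow 8041 and -1.30), eosinophil and basophil markers (0.24 and -1.73) and TLR signalling (0.03 and -0.43).

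Camera passed for these 12 lists, with an adjusted p of 8.27e-08 for ribosomal proteins, 8.32e-07 for oxidative phosphorylation, 1.33e-05 for granule proteins, 0.000206 for interferon-stimulated genes, 0.0084 for the TCA cycle, and between 0.0149 and 0.049 for the rest. None passed with a correlation estimated from the data: adjusted p = 0.621 with an estimated correlation, and 0.65 for platelet markers. Fry passed for 0 of 27. Limma called 0 of 13080 rows, with 504 at an unadjusted p under 0.05 (135 positive, 369 negative) where chance gives 654, and 0 in each alternative. Adjusted over the list alone, 2 granule genes passed, both positive, and 1 apoptosis gene, negative. The smallest p, each at an adjusted p of 0.999, belonged among others to CPB2 (-3.73 ± 0.78), LTF, the integrin ITGA6 (2.69 ± 0.52), the acute-phase protein ORM1 (2.58 ± 0.48), P2RY12 (-2.56 ± 0.43) and FAS (-1.74 ± 0.37). IL1B was at -1.63 ± 0.48 and IL1R2 at 2.01 ± 1.07. Without both arrays of cow 8041 the granule median was 0.53 (adjusted p = 0.0166), and 6 of the 12 lists passed; platelet markers (0.24, adjusted p = 0.812), cell cycle (0.19, adjusted p = 0.587), proteasome (adjusted p = 0.106), fatty acid and cholesterol synthesis (0.0845), eosinophil and basophil markers (0.0761) and glucocorticoid-responsive genes (0.0581) were lost, while T cell and NK markers (median -0.80, from -0.11), cytokines (-0.46, from -0.14) and adhesion (-0.38, from -0.17) passed there and not with all arrays.

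**Figure D3:**
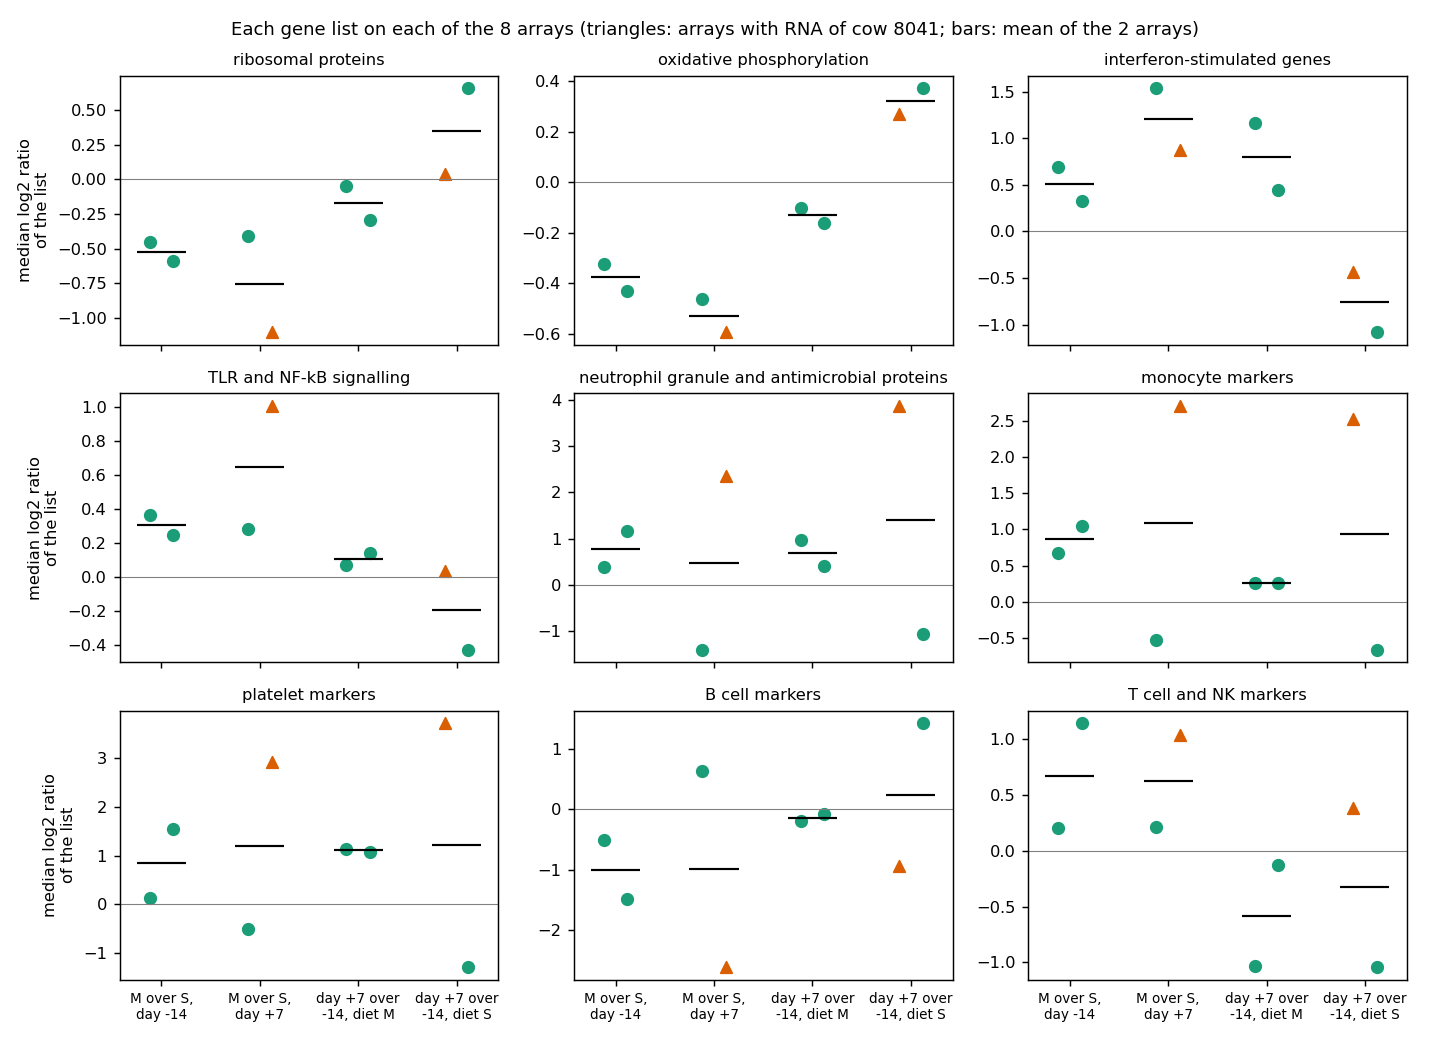
Median log2 ratio of the members of 9 gene lists (vertical axis) on each of the 8 arrays, grouped by what the array compared (horizontal axis); bars are the mean of 2 arrays and triangles are arrays with RNA of cow 8041. Ribosomal protein, oxidative phosphorylation and interferon-stimulated lists have the same sign on both arrays of each comparison, while granule proteins lie at 3.88 and -1.06 on the arrays of the days in diet S.

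The interaction asked whether the day difference depended on the diet. For interferon-stimulated genes it was positive in 20 of 23 (median log2 1.09, SD 0.69), from a median day difference of 0.62 in diet M and -0.59 in diet S. ISG20 was at 1.88 ± 0.39, HERC6 at 1.77 ± 0.30, IFIT5 at 1.62 ± 0.38 and IRF9 at 1.33 ± 0.33. Ribosomal proteins were negative in all 61 (median -0.44, SD 0.17) and oxidative phosphorylation genes in 63 of 74 (median -0.32, SD 0.26). Adhesion was positive in 16 of 20 (0.60; CXCR1 at 2.10 ± 0.64), TLR signalling in 22 of 32 (0.25; MYD88 at 1.57 ± 0.34), mature neutrophil markers in 9 of 12 (0.82; MXD1 at 2.12 ± 0.46), cytokines in 14 of 17 (0.68; IL1B at 1.65 ± 0.55) and glucocorticoid-responsive genes in 13 of 19 (0.32; SGK1 at 1.82 ± 0.58). Fatty acid and cholesterol synthesis was negative in 16 of 22 (-0.42; SQLE at -1.11 ± 0.36) and the TCA cycle in 18 of 21 (-0.32).

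Camera passed for these 10 lists, with an adjusted p of 2.79e-11 for interferon-stimulated genes, 1.08e-08 for ribosomal proteins, 9.49e-06 for oxidative phosphorylation, 0.000515 for adhesion, 0.00156 for both TLR signalling and mature neutrophil markers, 0.00388 for cytokines, 0.00445 for fatty acid and cholesterol synthesis, 0.00664 for glucocorticoid-responsive genes and 0.00805 for the TCA cycle. None passed with a correlation estimated from the data: adjusted p = 0.65 with an estimated correlation, and 0.665 for adhesion. Fry passed for 0 of 27 (adjusted p = 0.394 for interferon-stimulated genes). Limma called 0 of 13080 rows, and 0 in each alternative. At an unadjusted p under 0.05 there were 772 (622 positive, 150 negative), where 5% of the rows is 654. The unadjusted count was 646 as deposited and 482 without both arrays of cow 8041. Adjusted over the list alone, 8 interferon-stimulated, 3 mature neutrophil, 1 monocyte and 1 apoptosis gene passed, all positive. The smallest p, each at an adjusted p of 0.777, belonged among others to P2RY12 (2.69 ± 0.50), SEMA4D (2.41 ± 0.46), OLIG1 (2.31 ± 0.33), TMEM140 (2.12 ± 0.40) and DGAT2 (1.97 ± 0.36); LTF was at -1.98 ± 0.70. With cow 8041 left out, fatty acid and cholesterol synthesis (adjusted p = 0.0509) and glucocorticoid-responsive genes (adjusted p = 0.117) were lost.

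Averaged over both days, the comparison asked for a diet difference common to the time before and after calving. Ribosomal proteins were negative in all 61 (median log2 -0.64, SD 0.20) and oxidative phosphorylation genes in 69 of 74 (median -0.48, SD 0.29). Interferon-stimulated genes were positive in 20 of 23 (median 0.94, SD 0.58), TLR signalling in 26 of 32 (0.55), mature neutrophil markers in all 12 (1.07), monocyte markers in all 12 (1.04) and T cell and NK markers in 20 of 21 (0.55). NLRP3 had the smallest p of the named genes, at 2.54 ± 0.30 (adjusted p = 0.122), followed by POLE2 at -2.54 ± 0.32, P2RY12 at 2.45 ± 0.35 and MYD88 at 1.55 ± 0.24 (0.133 each). Camera passed for 19 of 27 lists, with an adjusted p of 3.95e-15 for ribosomal proteins, 5.32e-10 for oxidative phosphorylation and 1.68e-05 for interferon-stimulated genes. None passed with a correlation estimated from the data (adjusted p = 0.439 with an estimated correlation for these 3). Fry passed for oxidative phosphorylation (adjusted p = 0.0273), the TCA cycle and the proteasome (0.0376 each), and for 0 lists without both arrays of cow 8041. It also passed for 0 lists without any single array, except 2 without the second day -14 diet array. Limma called 0 of 13080 rows, with 3346 at an unadjusted p under 0.05 (1676 positive, 1670 negative) where 5% of the rows is 654. With the cow as block it called 0, with 2881. The unadjusted count was 2970 as deposited and 1212 without both arrays of cow 8041. Adjusted over the list alone, 9 interferon-stimulated, 9 TLR, 8 cytokine, 7 adhesion, 5 glucocorticoid-responsive, 5 mature neutrophil, 3 apoptosis, 3 monocyte, 2 eicosanoid, 2 T cell and NK and 2 eosinophil and basophil genes passed, all positive. So did 6 cell cycle genes, 1 RNA polymerase and 1 granule gene, all negative, and 1 gene of each sign among B cell markers and fatty acid oxidation. Without both arrays of cow 8041 the monocyte median was 0.41, the eosinophil and basophil median was 0.46 against 1.85 with them, and camera passed for 15 of the 19 lists; granule proteins (adjusted p = 0.823), B cell markers (0.398), platelet markers (0.187) and fatty acid and cholesterol synthesis (0.0715) were lost.

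Averaged over both diets, the comparison asked for a difference between days that the diets shared. Granule and antimicrobial proteins were positive in 19 of 20 (median log2 1.18, SD 0.97), with LTF at 2.15 ± 0.50. The diet S day arrays did not share this sign, with list medians of 3.88 with cow 8041 and -1.06 without it. On the diet M day arrays the medians were 0.96 and 0.42. T cell and NK markers were negative in 17 of 21 (median -0.33, SD 0.33) and eosinophil and basophil markers in 5 of 6 (-0.84). Platelet markers were positive in all 7 (0.72), monocyte markers in 9 of 12 (0.44), glycolysis in 20 of 22 (0.23), NADPH oxidase in 19 of 22 (0.12), ribosomal proteins in 46 of 61 (0.12), oxidative phosphorylation in 59 of 74 (0.10) and cell cycle in 16 of 24 (0.16). Camera passed for these 10, with an adjusted p of 3.35e-08 for granule proteins and 0.000253 for T cell and NK markers, and none passed with a correlation estimated from the data (adjusted p = 0.63 with an estimated correlation, 0.804 for ribosomal proteins). Fry passed for 0 of 27. Limma called 0 of 13080 rows, with 249 at an unadjusted p under 0.05 (121 of them negative) where 5% of the rows is 654. With the cow as block it called 0, with 316. The unadjusted count was 761 as deposited and 184 without both arrays of cow 8041. The smallest p belonged among others to FGF9 (2.36 ± 0.60), the complement gene C1QA (2.00 ± 0.47) and ORM1 (1.82 ± 0.39). Without both arrays of cow 8041 the granule median was 0.50 (adjusted p = 0.00343), the T cell and NK median was -0.85, and 4 lists passed. Platelet markers (median 0.05, adjusted p = 0.325), monocyte markers (-0.002, adjusted p = 0.908), glycolysis (0.13, adjusted p = 0.626), cell cycle (adjusted p = 0.436), NADPH oxidase (0.252) and oxidative phosphorylation (0.107) were lost. With the cow as block, cell cycle was lost (adjusted p = 0.0506).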

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

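Of the tests in this part, the counts over other splits of the cows and days were planned before their results were seen, and the tests on cow 8041, brightness and cell share were chosen afterwards.

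The interaction of diet and day passed camera with the preset correlation for 10 lists, so these lists stood apart from the other genes under that setting. None passed with an estimated correlation (adjusted p of 0.65 or 0.665) and fry passed for none of them. A day difference that depended on the diet is therefore not established. The medians of the interaction were 1.09 for interferon-stimulated genes, -0.44 for ribosomal proteins, -0.32 for oxidative phosphorylation, 0.60 for adhesion and chemotaxis and 0.25 for TLR and NF-kB signalling. They were 0.82 for mature neutrophil markers, 0.68 for inflammatory cytokines and chemokines, -0.42 for fatty acid and cholesterol synthesis, 0.32 for glucocorticoid-responsive genes and -0.32 for the TCA cycle. Fatty acid synthesis and glucocorticoid-responsive genes were lost without both arrays of cow 8041.

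Interferon-stimulated genes had opposite signs over days in diet M (0.62) and diet S (-0.59). The 2 arrays of cow 8041 as the whole source are argued against: without them the median interaction was 1.45 and camera still passed. A shift of all genes with brightness is argued against too, since in the values as deposited, where that trend is still present, the median of 1.09 exceeded 100% of 10000 random lists matched on brightness, whose central range ran from -0.30 to 0.17. The difference in diet that the design names stays open, as does a difference between the individual cows compared, since the days in diet S came from different cows on each array and no interaction passed with an estimated correlation.

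The diets at day +7 gave 3760 rows at an unadjusted p under 0.05. Among the 33 splits of the 8 cows into 4 and 4 that could be fitted (2 of 35 could not), 3 gave as many, the real one included. The others gave 5289 and 4826, so chance is not excluded. Both differed from the real split by only 2 cows that changed sides, so they would keep part of a diet difference. The next highest splits gave 3474 and 3154. All of these kept cows 8041 and 7472 on 1 side, and otherwise the highest count was 1989. With these cows together the count also fell as low as 81. Averaged over both days, 4 of 33 splits gave at least the real 3346 rows (highest other 5618), and for the days averaged over both diets 72 of 86 swaps of days within cows gave at least the real 249 (highest other 2491), so chance is not excluded for either. The other splits that reached 3346 (5618, 4597 and 3591) also differed from the real one by only 2 cows. For a dye bias that follows brightness, the count as deposited was 0.881 times the count after its correction. An uncorrected trend can also widen the spread and so lower the count, so this ratio cannot decide about that bias. With both arrays of cow 8041 left out, 10.3% of the rows lay under the threshold, against 28.8% with them. For independent, unchanged rows it would be 5%. Fewer arrays also lower such a share, so cow 8041 and the diet cannot be told apart here.

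Granule and antimicrobial genes were positive over days averaged over both diets (median 1.18). On the diet S day arrays the list median was 3.88 with cow 8041 and -1.06 without it. With both arrays of cow 8041 left out the averaged median was 0.50. That lay between the values that would have decided for or against that cow as the source. The cow and the days therefore cannot be told apart with the remaining arrays. An equal rise of all other cell types in the RNA of cow 8041, as 1 form of a lower share of granulocytes, is argued against. On both of its arrays the B cell median lay apart from the monocyte and platelet medians by 3.46 or more on the log2 scale. That is beyond the sum of their SDs over members (2.71 to 3.32), whichever dye is on top. The gap shows only that the other cell types did not move alike, so it cannot decide about a lower share as such. A lower share with more B cells alone was not tested, and a lower share stays open. With the partner over cow 8041, granule proteins were at 3.88 and B cell markers at -0.94 on its diet S day array. On its day +7 diet array they were at 2.36 and -2.62. For the partner over cow 8041, mature neutrophil markers were at 0.71 (SD over members 2.38) on its diet S day array. On its day +7 diet array they were at 2.15 (SD 1.09). A change of the cells with calving, which the design names, stays open.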

How the results depend on the processing

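The values as deposited (kept before any model was fitted), loess on each array's own brightness, the brightness minimums, the trend on brightness, the run without both arrays of cow 8041 and fry with single arrays or that cow left out were chosen after seeing the data; the other alternatives were planned. Without both arrays of cow 8041, some list medians changed sign. Monocyte markers did so for day in diet M (0.51, then -0.02) and in the day average (0.44, then -0.002), where camera no longer passed either. Several lists that had not passed did so too. Examples are eosinophil and basophil markers in the interaction (0.30, then -0.64), NADPH oxidase at day -14 (0.09, then -0.12) and apoptosis in diet S (0.20, then -0.03). The count of 1 for diet M versus diet S at day +7 was 2 with no dye term, 0 with arrays scaled to one spread, 0 with 1 row per probe, 0 with values on at least 7 arrays, 0 on direct arrays only, 0 without both arrays of cow 8041, 1181 at an adjusted p under 0.10 (812 positive, 369 negative), 43 as deposited, 36 and 361 at brightness minimums of 16 and 64, 498 and 702 at the next higher minimums tried, and 374 with a trend on brightness. As single arrays were left out it was 0 to 64; 64 came without the first day +7 diet array and 1 without the first day -14 diet array. A brightness minimum tests fewer rows; the cause of the other moves was not tested. As deposited all 43 were positive, at a minimum of 64 320 of 361, and with the trend 347 of 374; each included the unnamed feature 24090. Diet averaged over both days gave 1 at a minimum of 64, and 0 in the other alternatives. The other comparisons gave 0 throughout.

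With an estimated correlation 0 lists passed in each of the 7 comparisons. Fry passed for 6 lists for diet at day +7, 3 for diet averaged over both days and 0 for the others. With cow 8041 left out, 4 lists passed for day in diet M and 4 for the day average. As single arrays were left out, lists past camera ranged from 5 to 15 for day in diet M, 8 to 16 for day in diet S, 10 to 18 for diet at day -14, 13 to 19 for diet at day +7, 7 to 13 for the interaction, 15 to 20 for the diet average and 4 to 12 for the day average. Fry passed for 0 lists at day +7 without any 1 array, except 3 without the second day -14 diet array and 1 without the second day +7 diet array. For diet averaged over both days it passed for 0 lists without any 1 array, except 2 without the second day -14 diet array. Of 8420 recomputed values of named genes, 114 had the other sign. Dim spots may limit the precision, which was not tested: the median recovered brightness was 27.9 to 74.5 per array.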

Other observations

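All tests in this part were chosen after seeing the data.

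On the arrays of cow 8041, on diet S, several granule and acute-phase genes had large ratios, and others differed between its arrays. Turned so that the partner cow is over cow 8041, the cathelicidin CATHL2 was at 9.17 and 6.05, CATHL6 at 8.23 and 1.31, haptoglobin (HP) at 6.42 and 3.45, IL1R2 at 4.77 and 2.20 and LTF at 5.61 and 1.75 on the diet S day array and the day +7 diet array. Other genes had opposite signs on these arrays: LCN2 was at 3.47 and -2.05, ORM1 at 5.24 and -0.16, IL1B at -2.12 and 3.27 and FAS at -1.49 and 3.98. These genes were picked after their values were seen. B cell markers were at 0.94 and 2.62 for cow 8041 over its partner, while T cell and NK markers were at -0.39 and -1.03, on the side of the partner. The array of cow 8041 at day +7 had an SD of 1.49 after loess, against 0.58 to 0.88 on the others, its diet S day array (0.885) among them.

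Across all genes tested, the turned ratios of the 2 arrays of a pairing correlated at 0.347 for the diets at day -14, 0.102 for the diets at day +7, -0.0653 for the days in diet M and -0.135 for the days in diet S. Genes are not independent replicates. Over the bright rows alone, arrays that share a cow in opposite channels correlated at -0.621 (7472), -0.61 (7977), -0.265 (7979) and -0.0549 (7631), and those that share it in the same channel at 0.358 (8041) and -0.246 (7944), also across genes; 6 such pairs were computed.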
